A study of Sminthopsis crassicaudata with 6 samples.

How the data were processed

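Gene expression was measured by RNA sequencing in the developing neocortex of the fat-tailed dunnart (Sminthopsis crassicaudata), a small carnivorous marsupial of Australia, at postnatal days 12 and 20, called P12 and P20. Per the labels, P12 corresponds to stage 20 and P20 to stage 23, and 3 wild-type specimens were taken at each age, so each library comes from a different animal. Per the labels' protocols, neocortex from the left and right sides was dissected, RNA was extracted with TRIzol and treated with DNase, and each preparation reached an RNA integrity number of at least 8.6. From 400 ng of total RNA, ribosomal RNA was removed with Ribo-Zero, and stranded total-RNA libraries were made and read on a HiSeq 2000 as 125 bp read pairs. Because the libraries were not selected for polyadenylated RNA, they can hold unspliced and non-coding transcripts as well as messenger RNA.

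The deposited values are expected counts from RSEM, one per assembled gene and library, which the authors had not scaled for depth. Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt 1.18, RSEM 1.3.1 and edgeR, and per the series design text the reads of all samples were pooled and assembled de novo with Trinity. The Trinity version, the aligner under RSEM and the strand setting are not given in the sources used here, so reads of a transcript and its antisense partner may or may not have been told apart. RSEM divides a read that matches several transcripts among them, and 92.0% of the values were whole numbers within 0.001. The deposited table held 2246926 assembled genes, and a second file mapped the same genes to 2704138 transcripts. An assembled gene is a group of assembled transcripts judged by Trinity to share a locus, and the identifiers place the genes in 1629353 read clusters. A full-length messenger RNA can be broken into several assembled genes, close paralogs can share reads, and intronic or intergenic RNA can form assembled genes of its own. The counts of genes given here are therefore counts of assembled genes, which outnumber the genes of the genome.

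The files do not pair the identifiers with gene names, sequences, lengths or positions. None of them (0) was found among the identifiers and symbols of 28335 genes in the RefSeq annotation of assembly GCF_048593235.1. For this reason none of the 42 gene lists fixed before the data were examined, which covered progenitors, neuron classes, glia, synapses, signalling pathways and other tissues, was tested, and no genome coordinates are given. No sums per gene symbol were formed.

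Expected counts were rounded to whole numbers. The rounded totals were 58878086, 50031536 and 61937780 for P12 replicates 1, 2 and 3, and 25388238, 25525337 and 42797958 for P20 replicates 1, 2 and 3. Genes with enough counts for their age group were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), scaled by the trimmed mean of M values (TMM) and fitted with the robust quasi-likelihood model, with age as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and all directions are P20 relative to P12. CPM, the counts relative to a library total, of single genes and of abundance classes were computed from the deposited counts with TMM-scaled totals of the tested genes, and those of detected genes with the library totals. Standard errors of log2 fold changes were derived from the fold change and the quasi-likelihood F statistic. Values per library were compared between ages by exact two-sided permutation tests. With 3 libraries against 3 such a test cannot give a p under 0.1. Confidence intervals are 95% Wilson intervals of shares unless named otherwise, and a count of 0 was read against a floor of 3 counts over the 3 libraries of an age. Intervals and floors cover counting error only. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

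The rule for naming single genes, also fixed in advance, took the 2 largest rises and the 2 largest falls among changed assembled genes with a mean of at least 5 CPM and no overlap between the libraries of the 2 ages. It left 4033 rising and 4944 falling genes to choose from. Alternatives fixed in advance were other scalings (median of ratios, upper quartile, library totals), other filters, DESeq2, edgeR's exact test, limma-voom and a test against a 2-fold change. Also fixed in advance were a false discovery rate of 0.01 and the replicate number as a block. So were leaving out each library in turn for the counts of changed genes and for the named genes, and thinning of all libraries to the smallest total for the number of genes with at least 10 counts. Thinning for the other values, leaving out libraries for values other than these counts and the named genes, sums per read cluster, and all alternatives of the 8-fold counts in abundant genes were added after seeing the data.

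The model was tested on simulated counts for this comparison, drawn from the means and library sizes of the 6 libraries. Each gene had the spread between replicates fitted for its abundance, genes were independent, and rises and falls were planted in equal number. Differences in spread between genes of like abundance and reads shared between genes were not simulated. The shares that follow hold for these settings only. Of 200 planted changes, 192 were among the 356551 genes tested, and the model called 2.22% of those changed 1.5-fold, 27.7% at 2-fold, 76.0% at 4-fold and 98.0% at 8-fold, and 3 of the 356359 unchanged genes. Of 20000 planted changes, 19228 were among 357446 genes tested, and the shares were 13.6%, 48.1%, 95.8% and 99.98%, with 565 calls among 338218 unchanged genes. No call went in the wrong direction. Replicates of an age were checked for repeated deposits by a chi-square comparison of their counts. The statistic per degree of freedom was between 2.43 and 7.93 for the 6 pairs, above the value of 1 that sampling noise alone would give, so each library was counted as a separate sample.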

Results

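To follow the transcriptome of the marsupial neocortex as it develops in the pouch, rRNA-depleted total RNA was sequenced from 3 fat-tailed dunnart joeys at P12 and 3 at P20. The P12 libraries held between 50031536 and 61937780 counts, and the P20 libraries between 25388238 and 42797958. The P12 libraries were thus 1.97 to 2.44 times as deep as the smallest P20 library. Values for individual assembled genes are given by identifier, since the files do not pair identifiers with gene names.

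The 2 ages had distinct expression profiles. On log2(CPM + 0.5) values, the first principal component held 55.1% of the variance and placed the 3 P12 libraries on one side and the 3 P20 libraries on the other. The correlation across tested genes, which are not independent replicates, was 0.965 to 0.969 between P12 libraries, 0.945 to 0.961 between P20 libraries and 0.884 to 0.923 between ages. These values were not computed at equal depth, and 166565 of the tested genes had a mean below 0.5 CPM. Every P12 library was deeper than every P20 library, so depth ran along with age here, and its part was not tested. The second component, with 15.5% of the variance, mainly set P20 replicate 2 apart from P20 replicates 1 and 3. In the comparison of counts within an age, P12 replicate 3 differed more from P12 replicates 1 and 2 (chi-square per degree of freedom 7.93 and 7.05) than those did from each other (3.11).

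Between P12 and P20, 62852 of 382604 tested assembled genes (16.4%) changed, of which 32530 were higher and 30322 lower at P20. Among the changed genes the median size of change was 1.13 on the log2 scale, with a middle range from 0.83 to 1.53. Changes of at least 2-fold numbered 37991, with 19693 genes higher and 18298 lower at P20. These sizes depend on what could be detected. Below a mean of 0.5 CPM, 8213 of 8281 rises and 8285 of 8328 falls were at least 2-fold. With at least 1 CPM in 3 libraries, 12247 of 38852 changed genes were. In 98.8% of the changed genes all 3 libraries of one age lay above all 3 of the other, which passing the test made likely. Such separation held for 35.6% of all tested genes, where chance gives 10% if the libraries of a gene differ at random. Genes share the libraries and their depth, so the excess over 10% was not tested. The biological coefficient of variation was 0.183, and calls were made with edgeR's quasi-likelihood test at an adjusted p under 0.05. Which direction was the more frequent depended on the processing, since 51.8% of the changed genes were higher at P20 here, against 47.8% with upper quartile scaling, 35.6% with no filter on low counts, 58.5% with library totals and 58.9% with limma-voom, and 48.6%, 45.4% and 48.2% without P12 replicate 1, P12 replicate 3 and P20 replicate 3. At 2-fold or more, too, falls were the more frequent with upper quartile scaling, with no filter and with any 1 library left out other than P12 replicate 2. The number of changed genes was 41759 without P12 replicate 1, 38906 without P12 replicate 3, 39823 without P20 replicate 3 and 35141 with DESeq2, and 4428 genes, 1466 higher and 2962 lower, passed when a change of at least 2-fold was itself tested.

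The share of genes that changed was larger in the higher abundance classes. Among genes with a mean below 0.5 CPM, 9.97% changed, with 8281 higher and 8328 lower at P20. Of 95669 genes between 1 and 5 CPM, 23.9% changed, and 53.1% of these were higher at P20. Of the 19092 genes between 5 and 20 CPM, 36.5% changed, and 44.6% of these were higher. At 100 CPM or more, 46.6% of 536 genes changed, 125 in each direction. Rare genes have few counts behind them, so a change of a given size is harder to detect there.

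Large decreases outnumbered large increases. Among the 24633 abundant assembled genes, those with a mean of at least 5 CPM, 118 fell at least 8-fold from P12 to P20 and 2 rose as much, although 4076 rose and 4978 fell in this class by any amount. Over all tested genes, 1806 fell and 469 rose at least 8-fold. At 16-fold or more the numbers were 982 and 179, and at 64-fold or more 460 and 113. Most of the 8-fold changes were in rare genes, where few counts stand behind a fold change. Below a mean of 0.5 CPM, 1155 fell and 380 rose at least 8-fold. With at least 10 counts in every library, 114 fell and 10 rose as much, but this filter also removes genes absent at one age. Genes that fell at least 8-fold took 3.07% ± 0.421 of the counts at P12 (SD, n = 3) and 0.201% ± 0.0714 at P20 (SD, n = 3). Genes that rose at least 8-fold took 0.00258% ± 9.1e-05 at P12 and 0.0428% ± 0.00458 at P20 (SD, n = 3 each). Both groups were defined by their change in these libraries, which fixes the direction of their shares, so the shares were not tested. Falls exceeded rises with each library left out, but the counts over all tested genes moved. Rises numbered 1117, 1321 and 1069 without P12 replicates 1, 2 and 3 and 765 without P20 replicate 1, and falls numbered 3231, 2988 and 3728 without P20 replicates 1, 2 and 3.

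**Figure D1:**
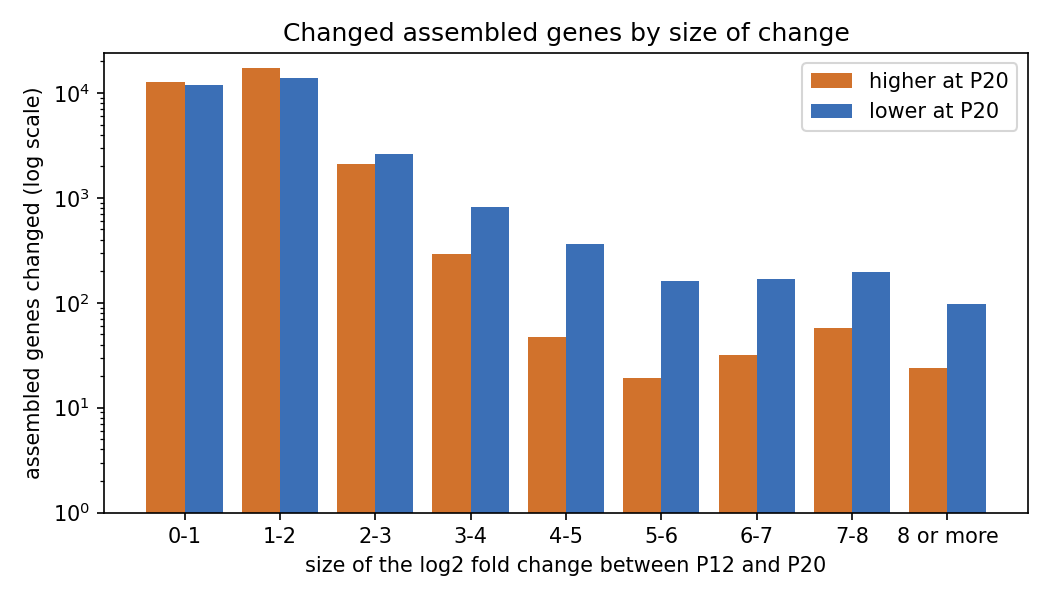
Number of changed assembled genes (log scale) by the size of their log2 fold change between P12 and P20, for genes higher (orange) and lower (blue) at P20. Bars for genes lower at P20 are the taller ones in every class from a log2 fold change of 2 upward, where 4426 genes fell and 2559 rose.

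Named by the rule fixed in advance, TRINITY_DN801164_c2_g1 and TRINITY_DN784249_c1_g3 had the largest rises among abundant genes. TRINITY_DN801164_c2_g1 went from 0.321 ± 0.144 CPM at P12 to 11.998 ± 0.559 CPM at P20 (SD, n = 3 each), a log2 fold change of 5.24 with a standard error of 0.22 (edgeR adjusted p = 3.7e-09). TRINITY_DN784249_c1_g3 went from 4.92 ± 2.46 to 87.3 ± 21.8 CPM (SD, n = 3 each), a log2 fold change of 4.15 with a standard error of 0.47 (edgeR adjusted p = 0.00768). The call for TRINITY_DN784249_c1_g3 was lost without P12 replicate 3 (edgeR adjusted p = 0.0552), with the replicate number as a block (adjusted p = 0.0573) and in edgeR's test against a 2-fold change (adjusted p = 0.0529), in a range from 6.9e-41 to 0.0573 over its 18 alternatives. Its fold change was positive in each of them, from 3.86 to 4.58 on the log2 scale.

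Under the same rule, which is limited to abundant genes, the largest falls were those of TRINITY_DN870241_c0_g1 and TRINITY_DN804491_c5_g1. TRINITY_DN870241_c0_g1 held 18.5 ± 3.14 CPM at P12 (SD, n = 3) and had 0 counts in the 3 P20 libraries against 2871 in the 3 P12 libraries. Set against a floor of 3 counts over the P20 libraries, 0.0338 CPM, it was at least 546-fold lower at P20 (edgeR adjusted p = 3.0e-09). TRINITY_DN804491_c5_g1 went from 19.8 ± 6.28 CPM at P12 to 0.0524 ± 0.0190 CPM at P20 (SD, n = 3 each), where it had 5 counts in all. It fell by 8.38 on the log2 scale with a standard error of 0.42 (edgeR adjusted p = 3.5e-06).

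**Figure D2:**
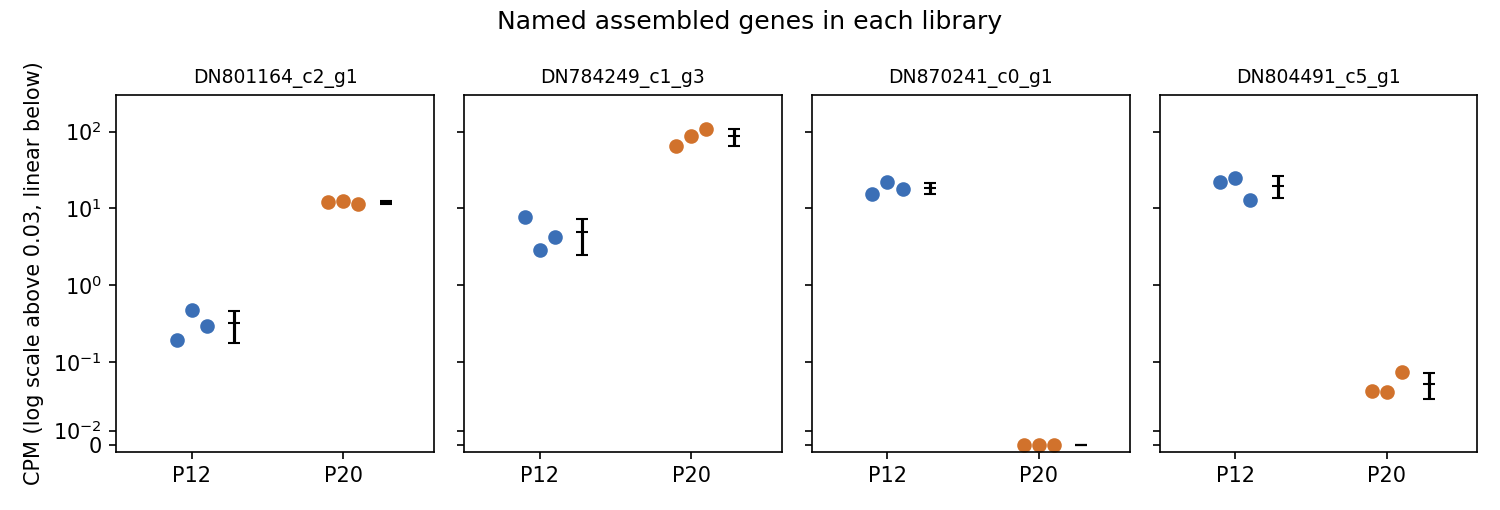
CPM of the 4 named assembled genes (with TRINITY left off the identifier) in each P12 (blue) and P20 (orange) library, on an axis that is logarithmic above 0.03 CPM and linear below. Bars give the mean and SD of 3 libraries, and in each gene all 3 libraries of one age lie above all 3 of the other, with TRINITY_DN870241_c0_g1 at 0 in the P20 libraries.

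The most abundant assembled genes changed in either direction. Of the 100 genes with the highest mean CPM, all above 334 CPM, 42 changed, 21 in each direction. Among these, 10 fell and 3 rose at least 2-fold, the largest fall being -6.01 and the largest rise 1.46 on the log2 scale. A single family of assembled genes shared the DN number of their identifiers, which can cover several read clusters. This family held 9.77% ± 1.31 of the counts at P12 and 12.002% ± 1.24 at P20 (SD, n = 3 each), with an exact permutation p of 0.2. Of its 61 tested members, 6 were higher and 12 lower at P20. The 100 most abundant genes of each library took 23.8% ± 2.63 of its counts at P12 and 22.6% ± 0.817 at P20 (SD, n = 3 each, exact permutation p = 0.4, where the smallest possible is 0.1). The difference of -1.12 percentage points was -0.349, -0.371 and -2.64 without P12 replicates 1, 2 and 3. Genes lower at P20 held 18.3% ± 0.0854 of the counts at P12 and 9.01% ± 0.754 at P20, and genes higher at P20 held 9.20% ± 0.167 and 16.4% ± 0.797 (SD, n = 3 each). These groups were defined by their change, so their shares were not tested.

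Few assembled genes were seen at one age only. With at least 1 CPM in each library of one age and 0 counts in each of the other, 36 genes were present at P12 alone and 11 at P20 alone. Of the 36, 35 were called lower at P20, and all 11 were called higher, which the way they were chosen made nearly certain. When libraries were thinned to the smallest total the numbers were 36 and 10. When 1 count per library was allowed in the absent age they were 64 and 11. The numbers followed the minimum level, being 102 and 23 at 0.5 CPM and 6 and 3 at 2 CPM. Patterns of 3 libraries that mix the ages held up to 8 genes at 1 CPM, 27 at 0.5 CPM and 4 at 2 CPM. The number at P12 alone exceeded this at each level, but the number at P20 alone did so only at 1 CPM. Summed over the 3 libraries of the age that had them, these genes held a median of 284 counts for P12 and 143 for P20, and a count of 0 over 3 libraries allows up to 3.

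Assembled genes with several transcripts differed from those with 1 transcript in the direction of change. Of all assembled genes, 90.7% had 1 transcript, and of those tested 244466 had 1 and 138138 had 2 or more. Among changed genes with 1 transcript 56.2% were higher at P20, against 45.8% of changed genes with 2 or more. Of tested genes with 1 transcript 14.6% changed (95% Wilson interval 14.5 to 14.8), and of those with 2 or more 19.6% changed (19.4 to 19.8). Genes of 1 locus or cluster are not independent, and the intervals cover counting only. When the classes were matched on abundance the shares that changed were 17.1% and 18.1%, while 55.8% and 47.0% of the changed genes were higher at P20. The transcripts were assembled from the pooled reads of these libraries, of which P12 supplied more. Whether genes higher at P12 therefore had more assembled transcripts was not tested, and matching on mean abundance does not address it. The difference in direction can thus not be assigned to the kind of gene.

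More assembled genes were detected at P12, and the difference followed depth. With at least 10 counts, 426763 ± 39247 genes were detected at P12 and 298869 ± 61377 at P20 (SD, n = 3 each), and every P12 library exceeded every P20 library (exact permutation p = 0.1, the smallest possible). After thinning to the smallest library the means were 253244 ± 11224 and 262421 ± 6371 (SD, n = 3 each, exact permutation p = 0.3), so the order of the ages was the opposite one. The excess at P20 of 9176 genes was 5649, 15648 and 5699 without P12 replicate 2, P12 replicate 3 and P20 replicate 2. At a minimum of 1 CPM, which scales with depth, 111094 ± 7281 genes were detected at P12 and 116460 ± 3232 at P20 (SD, n = 3 each, exact permutation p = 0.3). This difference of 5366 was 2763 without P12 replicate 2 and 9526 without P12 replicate 3. With 3 libraries at each age such a test cannot give a p under 0.1, so whether the ages differ in the number of expressed genes at equal depth stays open.

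**Figure D3:**
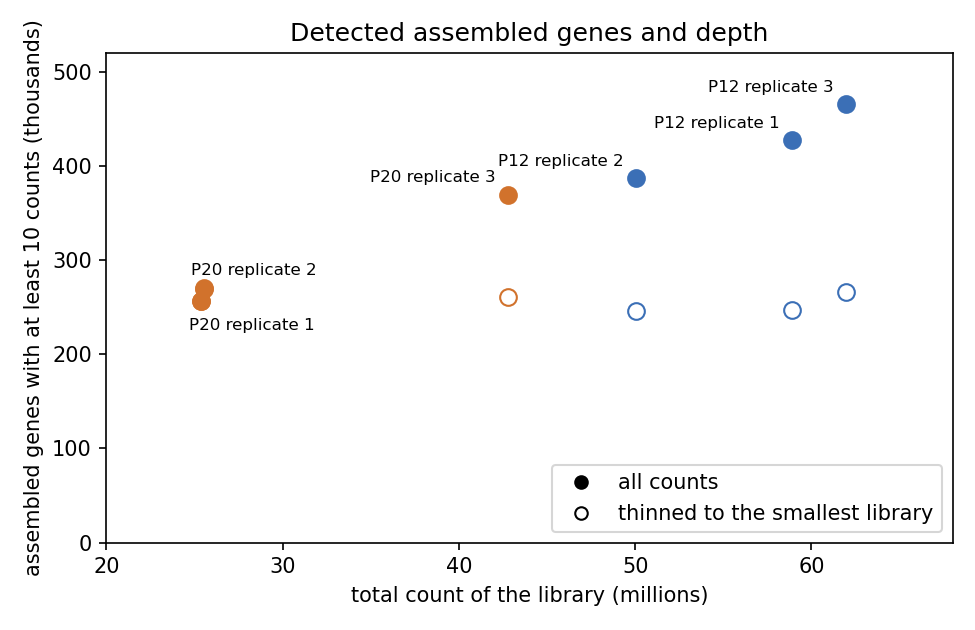
Assembled genes with at least 10 counts (number of genes, scaled as the axis states) against the total count of each library (counts, likewise scaled), for P12 (blue) and P20 (orange), with all counts (filled) and after thinning to 25388238 counts (open). Filled points climb from 256866 genes in the smallest library to 465594 in the largest, while the open points lie between 246190 and 269375; the open points of P20 replicates 1 and 2 lie under or beside their filled ones.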

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

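The alternatives were fixed before the data were examined, with exceptions chosen after seeing the data. These exceptions were thinning (other than of genes with at least 10 counts), sums per read cluster and the alternatives of the 8-fold counts. Leaving out libraries was also an exception, save for the counts of changed genes and the named genes. The number of changed assembled genes, 62852, stayed within 1.5 times under 13 of 19 alternatives. It was 38852 with at least 1 CPM in 3 libraries (fewer genes tested), 35141 with DESeq2 (the cause was not tested), 27281 at a false discovery rate of 0.01, and between 38906 and 47041 with 1 library left out (fewer samples). Changes of at least 2-fold, 37991, numbered 12247 with at least 1 CPM in 3 libraries and 17052 with at least 10 counts in every library. Both filters remove genes with few counts, and the second also removes those absent at one age. The number was 22420 with DESeq2 (the cause was not tested), 4428 when 2-fold was itself the tested threshold, and 26159 to 34590 with 1 library left out. Other scalings gave 60671 to 62855 changed genes and moved the median log2 fold change by less than 0.1. The 118 large falls among abundant genes were between 88 and 148 under 23 alternatives, against 1 to 10 rises.

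With replicate numbers as a block, 59531 genes changed, 55718 of them also changed without it, and 35736 changed at least 2-fold. Same-numbered libraries did not deviate together (r = 0.00768, 0.0965 and 0.0339 across genes), not every library correlated best with its own number, and the labels name different specimens, so the numbers do not pair the libraries. The adjusted p of TRINITY_DN784249_c1_g3 was 0.0573 with the block. The calls of the other named genes held in each alternative that tested them, 18 for TRINITY_DN801164_c2_g1 and 17 for each that fell, which the filter of 10 counts in every library removed.

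The lower number of genes with at least 10 counts at P20 reversed on thinning, to 9176 more at P20 (5649 to 15648 with 1 library left out), and that with at least 100 counts to 509 more (2.67 without P12 replicate 1, 1422 without P12 replicate 3). With at least 1 count the thinned difference, P20 relative to P12, was -3542, and it changed sign without P12 replicate 3 or P20 replicate 1 (exact permutation p = 0.3, 0.7 and 0.8 for the 3 thinned differences, where 0.1 is the smallest possible). The difference in the share of changed genes between genes of several and of 1 transcript, 4.98 percentage points, was 1.01 when matched on abundance, 4.08 with at least 1 CPM in 3 libraries, and 3.94 to 4.73 with 1 library left out. Tests of the gene lists and sums per gene symbol were not run, since the files do not pair identifiers with names.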

Other observations

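Tests of large falls against large rises, of presence in some libraries only and of read clusters, with all their settings, were chosen after those results were seen, and the counts over other splits of the libraries were planned.

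Assembled genes of 1 read cluster, which share sequence, mostly changed in the same direction. Changed genes lay in 59748 read clusters, and 2723 of these held at least 2 changed genes. Both directions occurred in 783 of them (28.8%), against a mean of 1431 ± 22.3 (52.5%) when directions were shuffled among these genes 100 times.

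The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The split by age was the only 1 of the 10 that reached its count, with 62852 changed genes against at most 9 in the other splits. For changes of at least 2-fold the numbers were 37991 and 9, again with 1 of 10 splits reaching the count. Each other split mixes the ages, so the difference between ages adds to the spread within its groups and leaves few calls. The low counts of those splits are therefore not a rate of false calls.

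Large falls outnumbered large rises, 1806 to 469 at 8-fold or more, a ratio of 3.85 that depended on the libraries, filter, test and unit used. It was 2.08, 1.58 and 2.10 without P12 replicates 1, 2 and 3 and 6.82 without P20 replicate 3. It was 2.19 with no filter, 10.04 with at least 1 CPM in 3 libraries, 11.4 with at least 10 counts in every library, 2.35 with limma-voom and 5.82 with counts summed per read cluster. Greater depth at P12 as the whole cause predicts a ratio near 1 after thinning. Among abundant genes the thinned ratio was 41.0 (123 falls and 3 rises). With each library left out, 97 or more falls stood against at most 4 rises. This argues against depth there, though genes of this abundance hold enough counts that thinning could change their fold changes little. Over all tested genes the thinned ratio was 4.995. It was between 1.67 (without P12 replicate 2) and 5.39 (without P20 replicate 3) with 1 library left out, where the unthinned values were 1.58 and 6.82. The jackknife standard error of the natural logarithm of the thinned ratio was 0.313 with deviations taken within each age. The left-out fits differ from the full thinned fit, since their filter kept 277569 to 287644 genes, against 256454. Each fit without a P12 library had a lower ratio, 1.67 to 2.17, and deviations within an age leave that shift out. Pooled over ages, which adds the difference between leaving out a P12 and a P20 library, the error was 0.947 and would not set the ratio apart from 1. The size of the ratio depended on which library was left out. Over all tested genes the ratio did not drop on thinning, but neither error settles whether depth was the whole cause. A few transcripts broken into many assembled genes could inflate one direction. Counted as read clusters that hold such a gene the ratio was 3.75 (1753 and 468), but this merged few of the genes, and pieces of a transcript that share no sequence lie in different clusters, so that explanation stays open. The assembly was made from pooled reads of which P12 supplied more, and whether it therefore holds more transcripts found mainly at P12 was not tested. A change with age in the cells or transcripts of the neocortex also stays open as a hypothesis.

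In P12 replicate 1 and P20 replicate 2, 59 assembled genes of 39 read clusters had at least 1 CPM, with 0 counts in the other 4 libraries, while no other of the 15 possible pairs of libraries shared more than 17 such genes. The excess was clearest at a higher minimum level, with 41 against at most 4 at 2 CPM, and at 0.5 CPM it was 87 against at most 74. Variant forms of 1 transcript assembled apart would leave a partner of opposite profile in the same cluster, found for 3.39% of these genes (95% exact interval 0.413 to 11.7) and for 54.1% (43.0 to 65.0) of the 85 genes of the other pairs of libraries, which argues against this. A single contaminant of fixed composition would give 1 ratio between the 2 libraries, but chi-square per degree of freedom against that was 18.0, above the 95th percentile for genes of matched count in each pair of libraries of the same age (6.32 to 12.6) and below the median of 26.8 for matched genes of these 2 libraries. DNA carried by only 2 of the specimens, such as a Y chromosome, is a candidate explanation that stays open, since sex is not given in the labels used here and the genes have no positions. Presence in the other 4 libraries only was not taken to decide on this explanation. At 1 CPM it held 13 genes against at most 10 in the other patterns of 4 libraries, and at 2 CPM 7 against at most 5. At 0.5 CPM it held 29 against up to 45. Of the 13, 23.1% (5.04 to 53.8) had a partner of opposite profile. None of the 59 (0) entered the test of the ages.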
